A study of Danio rerio with 25 samples.

How the data were processed

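RNA was measured in 25 libraries, each from a tube of 20 cardiomyocytes sorted by fluorescence from adult zebrafish hearts and prepared with Smart-seq2. Per the labels, the authors checked reads with FastQC 0.11.5, aligned them with HISAT2 2.1.0 to the GRCz11 build and assigned them to genes with featureCounts 1.6.0, and deposited raw read counts per Ensembl gene, unnormalised. The settings, the annotation release and the strand setting are not given in the sources used here, and the names of the deposited files follow the naming of a different aligner, so the files do not settle which tool made the counts. Each file held 31901 gene rows without a header, in whole numbers, and all 25 were read as counts. Gene names came from a table that names zebrafish genes in the human style where a human counterpart is known: 29178 IDs (91.5%) had a name, 2723 had none, and 6136 shared their name with another ID and are printed with it. No gene coordinates were available, so none are given. vmhcl, the gene of the reporter, matched no name, and vmhc is listed as MYH7.

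Libraries were grouped by the labels into CI_RFP (12), CI_BFP (3), UN_RFP (6) and UN_BFP (4), by cryoinjury or none and by the RFP or BFP gate. Replicates are numbered in the order of deposition. Total counts ran from 5644279 to 11981012. No library duplicated another: correlations of log2 CPM between pairs lay between 0.264 and 0.9. A gene not detected in any library of a group was set to a floor of 3 counts over the combined effective size of that group, 0.0313 CPM in CI_RFP, 0.107 in CI_BFP, 0.0589 in UN_RFP and 0.0641 in UN_BFP, and its fold is given as "at least". Reads without molecular identifiers are not independent molecules, so floors cover counting error only.

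The groupings, tests, gene lists, naming rule and other settings to try were fixed before the data were examined. Genes were kept by filterByExpr with the groups (14853 tested, 458 of them above 0 in every library), normalised by TMM and tested with edgeR 4.0.16 quasi-likelihood (robust, two-sided) in R 4.3.3. All 25 libraries entered one fit of 4 group means with 4 contrasts and the interaction of gate and injury. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The SE beside a gene's log2 fold change is the size of that change over the square root of the F statistic. It restates the p-value and was not estimated separately. Where a group held no count of a gene, the fitted log2 fold change and its SE are not bounded by the data and differ from the "at least" fold. The common biological coefficient of variation was 2.127.

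Gene lists fixed beforehand were sarcomere, calcium handling and excitation, cardiac transcription factors, dedifferentiation and border zone, neural crest, glia and pigment cells, cell cycle, glycolysis, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal proteins, extracellular matrix, fibroblast and epicardium, endothelium and endocardium, leukocytes and inflammation, erythrocytes, thrombocytes, immediate early and heat shock, unfolded protein response, hypoxia and growth factor signalling, and sorting line anchors. Each was tested with camera (limma 3.58.1, prior count 2) at a preset correlation of 0.01 against all other genes, with camera at an estimated correlation and with fry beside it, adjusted over the lists of a comparison. Counts "adjusted over the list alone" take the edgeR p-values of the list's members only. Totals, detected genes and percentages of counts were compared by exact two-sided permutation tests with Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, adjusted over 28 tests, of which 0 passed (the smallest adjusted p was 0.185). Named genes follow a rule. Among genes past the threshold, with a usable symbol and a count in at least 75% of the libraries of the higher group, the 8 higher and 8 lower of smallest p were named. Where fewer than 3 passed, the next by p were added up to 3 and said not to have passed. From each list described, up to 4 members past the threshold or else the 1 of smallest p were named, and the anchors were always given.

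The pipeline was tested on simulated counts, drawn from the mean of each gene over all libraries and its fitted spread, with the largest dispersions capped. Genes were drawn independently, so the simulation lacks any structure that genes share across the real libraries. Its false calls may therefore be too few: other splits of the real libraries gave up to 537 edgeR calls in CI_RFP vs UN_RFP. With no changed gene, edgeR called 0, 3, 5, 0 and 1 of 13899 genes in the 5 comparisons, voom 19, 7, 5, 5 and 2, and DESeq2 353, 175, 105, 241 and 270. Of genes changed 256-fold, edgeR recovered 12 of 46 in CI_RFP vs CI_BFP, 13 of 43 in UN_RFP vs UN_BFP, 40 of 47 in CI_RFP vs UN_RFP and 6 of 46 in CI_BFP vs UN_BFP. Of genes changed 16-fold it recovered 1 of 46, 0 of 46, 3 of 48 and 0 of 47, so at this spread most real differences of that size would be missed.

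The other settings fixed beforehand were DESeq2 1.42.0, limma voom with sample quality weights, RLE and TMMwsp factors, no filter on low counts, a stricter filter (10 CPM in at least 5 libraries), a fit of only the groups compared, robust=FALSE, log2 detected genes as a covariate, leaving out 3 libraries with under 0.5 of the median number of detected genes (CI_RFP 5, UN_RFP 1 and UN_RFP 5), leaving out mitochondrially encoded genes, leaving out each library in turn, a count of at least 5 for detection, a prior count of 0.5 and a threshold of 0.1 for the agreement of comparisons. Settings chosen after seeing the data were voom without those 3 libraries, voom with the detected-gene covariate, exact permutation of list means, a threshold of 0.1 for the agreement of the injury differences, and the log2 ratio of vmhc to myh6 per library (1 CPM added to each) as a covariate. That ratio is measured from genes that are themselves tested.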

Results

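The series profiled cardiomyocytes of adult zebrafish hearts. In the line used, a tamoxifen-inducible Cre recombinase is driven by sox10, a transcription factor gene of the neural crest. Its vmhcl reporter switches from blue tagBFP to red mCherry after recombination. Red cells therefore carry a history of sox10-driven recombination. Each library was made with Smart-seq2, a full-length cDNA protocol without molecular identifiers, from a tube of 20 sorted cells, and its reads were counted per gene. The 25 libraries fall into 4 groups: 12 from the RFP gate after cryoinjury (CI_RFP), 3 from the BFP gate after cryoinjury (CI_BFP), 6 from the RFP gate of uninjured hearts (UN_RFP) and 4 from the BFP gate of uninjured hearts (UN_BFP). Total counts per library ran from 5644279 to 11981012, with a median of 8802372. Between 1226 and 15380 genes had a count of at least 1, with a median of 10261. No label gives the animal, the sort or the day of a library, so each p-value measures only the spread between these libraries, which may be technical. Levels are in CPM, counts scaled to a common library size after TMM normalisation, and are given as mean ± SD. Gene list means are in log2 CPM.

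The genes that define the sort and the cardiomyocyte were read first. SOX10 mRNA was detected in 12 of 12 CI_RFP libraries at 7.04 ± 13.5 CPM and in 0 of 3 CI_BFP libraries (edgeR adjusted p = 0.524, voom adjusted p = 0.0123). CI_RFP 10 alone held 48.41 CPM, and CI_RFP 5, at 0.07279 CPM, lay below the CI_BFP floor of 0.1068 CPM. In uninjured hearts SOX10 was detected in 4 of 6 UN_RFP libraries at 12.8 ± 21.9 CPM and in 2 of 4 UN_BFP libraries at 4.41 ± 8.06 CPM (edgeR adjusted p = 0.931). The general cardiomyocyte genes MYL7, a regulatory myosin light chain of the heart, and HAND2, a heart transcription factor, were present in every group. MYL7 stood at 29120 ± 32690 CPM in CI_RFP, 6571 ± 4259 in CI_BFP, 16700 ± 14390 in UN_RFP and 4131 ± 3553 in UN_BFP. HAND2 stood at 156.8 ± 129 CPM, 54.2 ± 36.1 CPM, 125.2 ± 105.6 CPM and 123.6 ± 106.8 CPM in the same order. The cardiac transcription factor NKX2-5 stood at 73.1 ± 77.2, 8.79 ± 7.91, 51.4 ± 52.2 and 15.6 ± 21.3 CPM, and gata4 at 2.996 ± 4.38, 3.83 ± 5.36, 4.38 ± 6.14 and 3.76 ± 3.12 CPM. None of MYL7, HAND2, NKX2-5 and gata4 passed the edgeR test in any of the 5 comparisons, and each of the 4 turned in direction under some alternative in at least 1 comparison.

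Within the RFP gate, libraries held one chamber's myosin heavy chain and hardly any of the other. vmhc, the ventricular gene (listed as MYH7), exceeded myh6, the atrial gene, in 4 of 12 CI_RFP and 4 of 6 UN_RFP libraries. In those 8 libraries vmhc lay between 1580 and 53550 CPM and myh6 was at most 6.55 CPM. In the other 10 RFP-gate libraries myh6 lay between 238.7 and 4334 CPM and vmhc was at most 86.8 CPM. IRX1 (ENSDARG00000101831), a ventricular transcription factor, exceeded 1 CPM in 7 of the 8 libraries with more vmhc and in 0 of the 10 with more myh6. NR2F1 (ENSDARG00000052695), an atrial transcription factor, exceeded 1 CPM in 0 of the 8 and in 8 of the 10. In the BFP gate vmhc exceeded myh6 in 3 of 3 CI_BFP libraries, at 161.5 to 296.5 CPM, and in 3 of 4 UN_BFP libraries, at 107.1 to 3278 CPM. In these 3 CI_BFP libraries IRX1 exceeded 1 CPM in 0 and NR2F1 in 1, so the vmhc to myh6 ratio does not settle their chamber. In these 3 UN_BFP libraries IRX1 exceeded 1 CPM in 2 and NR2F1 in 0. The mean of 34 tested extracellular matrix genes lay between -1.85 and 0.99 in the 8 RFP-gate libraries with more vmhc and between -1.24 and 8.66 in the 10 with more myh6. In BFP-gate libraries with more vmhc it lay between 4.1 and 6.66 (3 CI_BFP) and between 2.7 and 6.14 (3 UN_BFP). Low matrix means thus went with vmhc in the RFP gate only. The group means of vmhc were 12670 ± 19760 CPM in CI_RFP, 233.7 ± 68.0 in CI_BFP, 8212 ± 9899 in UN_RFP and 962.5 ± 1556 in UN_BFP. Those of myh6 were 1429 ± 1577, 0.735 ± 1.27, 260.4 ± 406.6 and 23.1 ± 46.2 CPM in the same order. Neither gene passed the edgeR test in any comparison. vmhcl, the gene of the sorting reporter, matched no name. Its level in the RFP-gate libraries with more myh6 could therefore not be read, and no label names the chamber of a tube. These chamber genes were singled out after their values were seen, and the libraries so parted were not tested against each other.

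**Figure D1:**
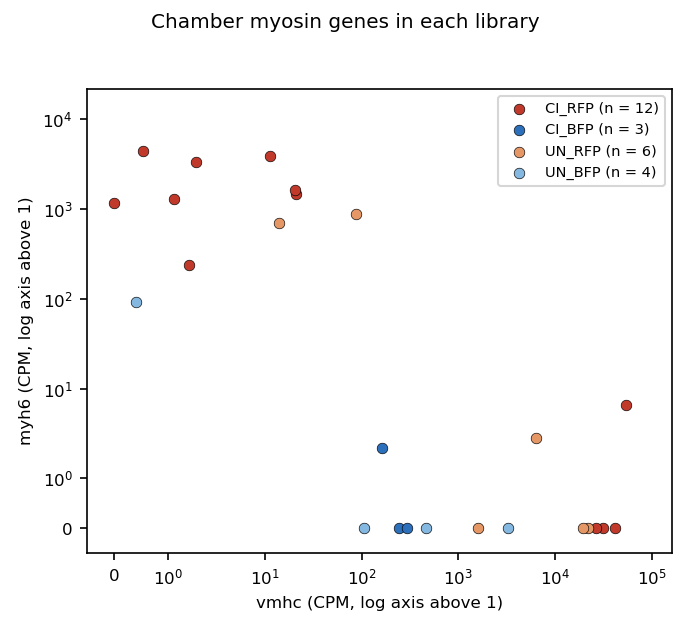
Each point is a library, with vmhc (MYH7) on the x axis and myh6 on the y axis, both in CPM on axes that are linear near 0 and logarithmic above, by group. The RFP-gate libraries sit along one axis or the other: 8 with vmhc at 1580 CPM or more and myh6 at most 6.55 CPM, and 10 with myh6 at 238.7 CPM or more and vmhc at most 86.8 CPM.

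After cryoinjury, the comparison of CI_RFP with CI_BFP asks how sox10-lineage cardiomyocytes differ from the cells of the BFP gate. Genes of contraction and excitation had higher means in the RFP gate, and leukocyte genes in the BFP gate. nppa, encoding atrial natriuretic peptide, stood at 1962 ± 2000 CPM in CI_RFP (n = 12) and 21.4 ± 13.9 CPM in CI_BFP (n = 3), 91.5-fold higher (log2 6.52, SE 1.48, edgeR adjusted p = 0.0629). PFKM (ENSDARG00000060797), the muscle phosphofructokinase of glycolysis, was found in 12 of 12 CI_RFP libraries at 140.7 ± 154.4 CPM and in 0 of 3 CI_BFP libraries, at least 1317-fold higher (edgeR adjusted p = 0.0629). FHL2 (ENSDARG00000003991), a LIM-domain protein of the sarcomere, followed at 93.8 ± 97.1 CPM against 0 of 3 libraries, at least 878.3-fold higher (edgeR adjusted p = 0.0629). These 3 genes had the smallest p among the higher genes and did not pass the threshold.

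The cardiac genes named next pointed the same way. Not all did: 5 of 19 cardiac transcription factors had a negative fold, and gata4 had a lower mean in CI_RFP. TBX20, a T-box factor of the heart, stood at 158.8 ± 88.3 CPM in CI_RFP and 0.381 ± 0.660 CPM in CI_BFP, 416.5-fold higher (edgeR adjusted p = 0.104, voom adjusted p = 8.32e-06). TBX5, also a T-box factor, was detected in 12 of 12 CI_RFP libraries at 38.9 ± 27.2 CPM and in 0 of 3 CI_BFP libraries (edgeR adjusted p = 0.224, voom adjusted p = 8.32e-06). RYR2, the calcium release channel of the sarcoplasmic reticulum, stood at 162.1 ± 79.8 against 0.127 CPM (edgeR adjusted p = 0.165, voom adjusted p = 2.86e-05). nppb, also a natriuretic peptide gene, stood at 2912 ± 2763 against 8.09 ± 11.3 CPM (edgeR adjusted p = 0.524, voom adjusted p = 0.0238). The 3 lower genes of smallest p under the same conditions did not pass the threshold. They were ADAM11, a disintegrin family member, F2R (ENSDARG00000086236), a thrombin receptor, and PSAP, the saposin precursor of lysosomes. At an edgeR adjusted p under 0.1 there were 10 lower genes, so others outside these conditions had a smaller p than F2R. ADAM11 was found in 3 of 3 CI_BFP libraries at 14.8 ± 14.2 CPM and in 0 of 12 CI_RFP libraries, at least 472.8-fold lower in the RFP gate (edgeR adjusted p = 0.0629). F2R stood at 0.00607 CPM in CI_RFP and 6.13 ± 8.01 CPM in CI_BFP (edgeR adjusted p = 0.152), and PSAP at 596.3 ± 610.1 and 4129 ± 3160 CPM (edgeR adjusted p = 0.269).

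The list of sorting line anchors ranked above other genes (6.57 ± 1.06 in CI_RFP, 2.47 ± 0.55 in CI_BFP, camera adjusted p = 1.54e-08). It was the 1 list of this comparison that passed with an estimated correlation (adjusted p = 0.0287). Its tested members were SOX10, vmhc, MYL7, myh6, TBX20, TBX5, gata4, HAND2, NKX2-5, nppa and nppb. Each also belongs to the sarcomere, cardiac transcription factor, dedifferentiation or neural crest list, so the anchors are not evidence apart from those lists. By fry, which tests the members' own change, this list (adjusted p = 0.00233), the calcium handling list (adjusted p = 0.0281) and the sarcomere list (adjusted p = 0.0418) passed, and the other 19 did not. Of its 11 tested members 10 had a positive fold, 0 passed over all genes and 5 were higher adjusted over the list alone. Calcium handling and excitation genes ranked above other genes (4.36 ± 1.61 against 0.54 ± 0.43, camera adjusted p = 3.03e-13, adjusted p = 0.104 with an estimated correlation). All 22 of 22 members were positive, and 7 were higher adjusted over the list alone. Sarcomere genes ranked above other genes (6.76 ± 1.67 against 3.76 ± 0.70, camera adjusted p = 1.51e-12, adjusted p = 0.161 with an estimated correlation). Of these 32 of 33 were positive and 10 were higher adjusted over the list alone. TNNT2 (ENSDARG00000020610), cardiac troponin T, stood at 6348 ± 5999 against 384.6 ± 167.4 CPM (edgeR adjusted p = 0.212). Nuclear oxidative phosphorylation genes ranked above as well (64 of 64 positive, camera adjusted p = 7.77e-09, adjusted p = 0.544 with an estimated correlation). Among them cox7a1, a cytochrome oxidase subunit, stood at 179.5 ± 243.7 against 8.73 ± 5.13 CPM. So did fatty acid oxidation genes (30 of 31 positive, camera adjusted p = 6.02e-06, adjusted p = 0.413 with an estimated correlation), where cpt1ab, a carnitine palmitoyltransferase that admits fatty acids to mitochondria, stood at 67.8 ± 54.8 against 0.0318 CPM (edgeR adjusted p = 0.212, voom adjusted p = 1.3e-05).

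Leukocyte and inflammation genes ranked below other genes in the RFP gate (1.48 ± 3.06 in CI_RFP, 6.13 ± 0.89 in CI_BFP, camera adjusted p = 1.38e-17, adjusted p = 0.279 with an estimated correlation). Of 42 members 36 had a negative fold, 0 passed by edgeR, also adjusted over the list alone, and 24 were lower by voom. spi1a, a myeloid transcription factor, stood at 10.4 ± 16.5 CPM in CI_RFP and 375.5 ± 330.2 CPM in CI_BFP (edgeR adjusted p = 0.524, voom adjusted p = 0.000698). The list took 0.289 ± 0.485% of counts in CI_RFP (n = 12) and 1.98 ± 1.14% in CI_BFP (n = 3; exact permutation p = 0.00659, adjusted p = 0.185). Endothelial genes also ranked below (24 of 29 negative, camera adjusted p = 8.51e-06, adjusted p = 0.413 with an estimated correlation). The fibroblast list (2.92 ± 3.82 against 3.76 ± 1.70, adjusted p = 0.293) and the extracellular matrix list (4.04 ± 4.19 against 5.06 ± 1.39, adjusted p = 0.153) did not pass. Their means were lower in CI_RFP, although 14 of 22 fibroblast and 27 of 34 matrix members had a positive edgeR fold.

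Glycolysis (camera adjusted p = 0.00458), cardiac transcription factor (0.00136), dedifferentiation and border zone (0.00839), hypoxia and growth factor (0.0416) and ribosomal protein lists (0.000437) ranked above other genes. In that order they had adjusted p = 0.567, 0.413, 0.413, 0.645 and 0.665 with an estimated correlation. Without CI_BFP 1 the glycolysis (adjusted p = 0.0507) and dedifferentiation lists (0.0671) no longer passed, and without any 1 of CI_BFP 2, CI_RFP 5, CI_RFP 6, CI_RFP 10 or UN_RFP 5 the hypoxia list did not (0.0514 to 0.117), nor without the 3 libraries of few detected genes (0.0821). Cell cycle genes did not pass (adjusted p = 0.137), with MCM6 (ENSDARG00000057683), a DNA replication helicase subunit, at 0.367 against 38.3 ± 36.4 CPM. Mitochondrially encoded genes did not pass (adjusted p = 0.137), with MT-ATP6, an ATP synthase subunit, at 7322 ± 7757 against 2016 ± 1095 CPM. Immediate early and heat shock genes did not pass (adjusted p = 0.0901), with the chaperone hsp90aa1.1 at 6352 ± 5815 against 144.3 ± 48.6 CPM. Nor did the neural crest list (adjusted p = 0.153), where the endothelin receptor ednrab was detected in 10 of 12 against 0 of 3 libraries. The erythrocyte (adjusted p = 0.0753), unfolded protein response (0.153), glia and pigment cell (0.293) and thrombocyte lists (0.511) did not pass.

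edgeR called 0 genes in this comparison (1136 higher and 249 lower at an unadjusted p under 0.05), voom called 456 higher and 352 lower, and DESeq2 called 445 and 12. Without 1 library edgeR called 9 genes (UN_BFP 4), 8 (UN_BFP 3), 7 (UN_RFP 2), 5 (CI_BFP 1), 4 (CI_RFP 11), 2 (UN_BFP 1 or UN_RFP 1) or 1 (CI_BFP 2, UN_BFP 2, UN_RFP 3 or UN_RFP 6). With the vmhc to myh6 ratio of each library in the model, an alternative chosen after seeing the data, edgeR called 25 higher and 114 lower genes. The higher ones included PFKM (adjusted p = 0.00602), nppa (adjusted p = 0.00581), FHL2 (adjusted p = 0.0159), TBX20 (adjusted p = 0.0312) and RYR2 (adjusted p = 0.0266). In that model the sarcomere (adjusted p = 0.0310 with an estimated correlation) and calcium lists (adjusted p = 0.0368 with an estimated correlation) passed.

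**Figure D2:**
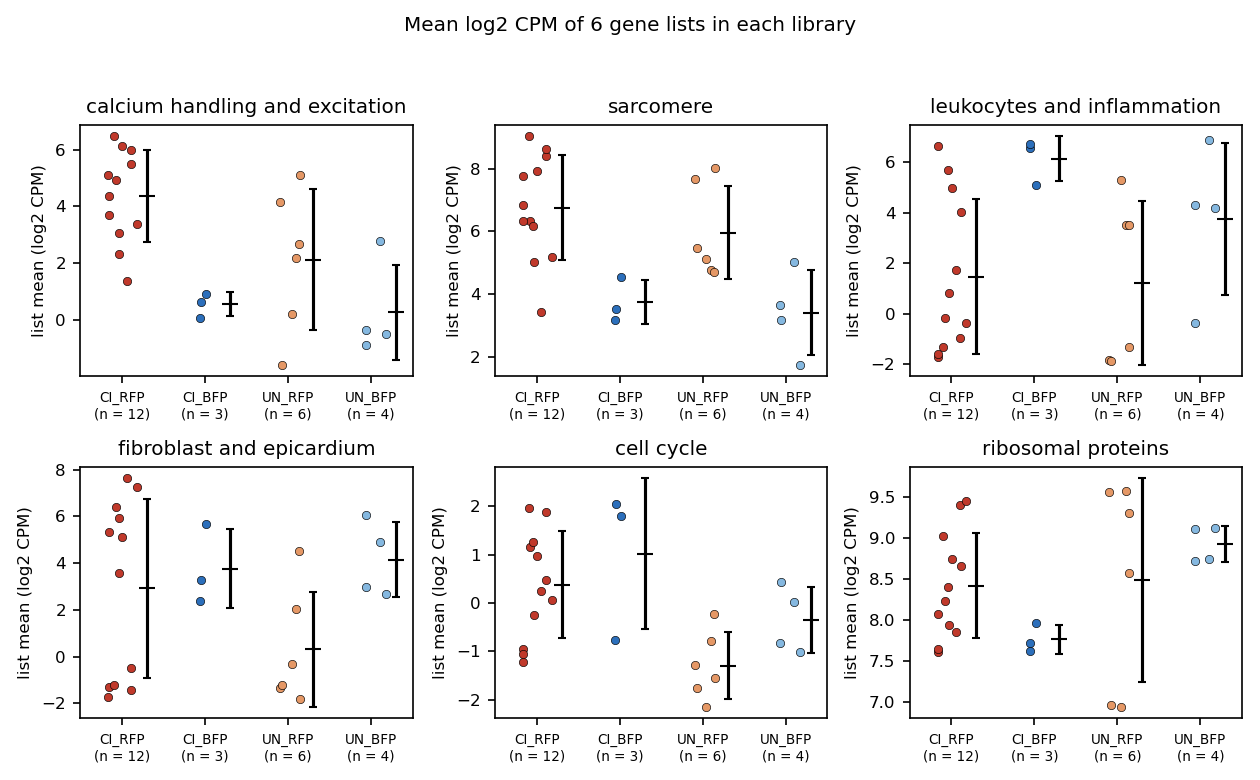
The mean log2 CPM of the tested genes of each list is drawn per library on the vertical axis, by group, with the group mean and SD. Calcium handling genes lie at 4.36 ± 1.61 in CI_RFP and 0.54 ± 0.43 in CI_BFP, and leukocyte genes at 1.48 ± 3.06 and 6.13 ± 0.89.

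In uninjured hearts, the comparison of UN_RFP with UN_BFP asks the same question before injury. Sarcomere genes again had higher means in the RFP gate, and fibroblast, matrix and endothelial genes had lower means. Fewer genes were detected on average in UN_RFP (6668 ± 3526 against 9566 ± 2487, exact permutation p = 0.205, adjusted p = 0.492). The 50 most counted genes took 62.7 ± 17.8% of counts there against 44.4 ± 6.69% (exact permutation p = 0.105, adjusted p = 0.438). MYBPC3, cardiac myosin-binding protein C, stood at 1612 ± 1702 CPM in UN_RFP (n = 6) and 93.6 ± 66.1 CPM in UN_BFP (n = 4), 17.2-fold higher (log2 4.11, SE 1.17, edgeR adjusted p = 0.115). nppa stood at 823.7 ± 971.4 against 44.4 ± 35.2 CPM, 18.6-fold higher (edgeR adjusted p = 0.115), and nppb at 832.1 ± 870.6 against 87.0 ± 153.5 CPM (edgeR adjusted p = 0.456). mlip, a muscle protein that binds lamin, stood at 133.9 ± 226.2 against 0.381 ± 0.259 CPM (edgeR adjusted p = 0.115), with UN_RFP 5 at 588.2 CPM. TBX20 (50.7 ± 45.3 against 34.04 ± 46.4 CPM, edgeR adjusted p = 0.981) and TBX5 (17.5 ± 24.4 against 1.98 ± 2.55 CPM, edgeR adjusted p = 0.477) were further from the threshold.

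The 3 lower genes of smallest p did not pass either. gbp, encoding a protein that binds glycogen synthase kinase 3, was detected in 0 of 6 UN_RFP libraries and in 3 of 4 UN_BFP libraries at 24.6 ± 18.2 CPM, at least 417.0-fold lower in the RFP gate (edgeR adjusted p = 0.0764). PTGS2 (ENSDARG00000010276), a cyclooxygenase of prostaglandin synthesis, stood at 0.0373 CPM in UN_RFP and 99.3 ± 124.1 CPM in UN_BFP (edgeR adjusted p = 0.0764, voom adjusted p = 0.00692). tspan34b, a tetraspanin, was detected in 0 of 6 and 4 of 4 libraries, at 42.8 ± 41.4 CPM in UN_BFP (edgeR adjusted p = 0.115, voom adjusted p = 0.0155).

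By fry no list of this comparison passed (the smallest adjusted p was 0.193, for the sarcomere and endothelial lists). Sarcomere genes ranked above other genes in UN_RFP (5.96 ± 1.49 against 3.42 ± 1.35, camera adjusted p = 1.1e-20, adjusted p = 0.0802 with an estimated correlation), with 30 of 33 positive and 6 higher adjusted over the list alone. Calcium handling genes also ranked above (20 of 22 positive, camera adjusted p = 7.12e-10, adjusted p = 0.169 with an estimated correlation). The sorting line anchors ranked above with 11 of 11 positive and 1 higher adjusted over the list alone (camera adjusted p = 8.08e-06, adjusted p = 0.0802 with an estimated correlation). atp2a2a, the calcium pump of the sarcoplasmic reticulum, stood at 1073 ± 1006 against 179.6 ± 215.5 CPM (edgeR adjusted p = 0.131). Lists of energy supply ranked above: nuclear oxidative phosphorylation (63 of 64 positive, camera adjusted p = 7.6e-09), mitochondrially encoded (13 of 13 positive, camera adjusted p = 4.04e-06), glycolysis (camera adjusted p = 1.39e-05) and fatty acid oxidation (camera adjusted p = 0.000133). Each had adjusted p = 0.506 with an estimated correlation. cox7a1 stood at 347.9 ± 362.8 against 28.5 ± 14.4 CPM, and MT-CO2, a mitochondrially encoded cytochrome oxidase subunit, at 42550 ± 32240 against 13360 ± 7589 CPM.

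Fibroblast and epicardium genes ranked below other genes in UN_RFP (0.31 ± 2.47 against 4.14 ± 1.61, camera adjusted p = 8.07e-05, adjusted p = 0.506 with an estimated correlation). Of these 21 of 22 were negative and 2 were lower adjusted over the list alone. PRRX1 (ENSDARG00000033971), a mesenchymal homeobox factor, was detected in 0 of 6 UN_RFP libraries and stood at 20.3 ± 31.2 CPM in UN_BFP (edgeR adjusted p = 0.115). Extracellular matrix genes ranked below (0.96 ± 2.82 against 4.82 ± 1.54, camera adjusted p = 4.36e-05, adjusted p = 0.537 with an estimated correlation). Of these 29 of 34 were negative and 1 was lower adjusted over the list alone. The 4 UN_RFP libraries with more vmhc had matrix means of -1.22 to -0.56 and fibroblast means of -1.80 to -0.30. UN_RFP 3 and UN_RFP 6, with more myh6, stood apart at 4.19 and 4.97 for matrix and 2.03 and 4.51 for fibroblast genes. COL6A2, a collagen VI chain, stood at 0.692 ± 1.36 against 63.5 ± 47.9 CPM (edgeR adjusted p = 0.115). Endothelial (camera adjusted p = 2.07e-06), unfolded protein response (0.000952), immediate early (0.00279) and leukocyte genes (0.00933) ranked below, and erythrocyte genes above (0.0316). In that order they had adjusted p = 0.506, 0.506, 0.542, 0.722 and 0.506 with an estimated correlation. The chemokine ccl34b.1 was detected in 0 of 6 UN_RFP libraries and stood at 12.6 ± 18.1 CPM in UN_BFP. Leaving out 1 library ended the call of the leukocyte list (UN_RFP 2, UN_RFP 4, UN_BFP 2, UN_BFP 3 or UN_BFP 4, adjusted p = 0.0592 to 0.351), the immediate early list (UN_RFP 5, 0.0729) and the erythrocyte list (CI_RFP 4, CI_BFP 2, CI_BFP 3, UN_BFP 1, UN_BFP 3, UN_RFP 2 or UN_RFP 5, 0.0522 to 0.107). Without the 3 libraries of few detected genes the immediate early (adjusted p = 0.904), mitochondrially encoded (0.133), erythrocyte (0.0757) and unfolded protein response lists (0.063) no longer passed. The dedifferentiation (adjusted p = 0.0914), thrombocyte (0.0958), ribosomal protein (0.327), cardiac transcription factor, hypoxia and neural crest (0.7102 each), glia and pigment cell (0.844) and cell cycle lists (0.942) did not pass. The cell cycle mean was lower (-1.29 ± 0.70 against -0.34 ± 0.69) although its test pointed up, and 8 members were lower adjusted over the list alone. CCND1, a cyclin of cell cycle entry, was detected in 0 of 6 UN_RFP libraries and stood at 15.6 ± 17.9 CPM in UN_BFP (edgeR adjusted p = 0.115). Means and tests also differed in sign for the dedifferentiation (0.50 lower), cardiac transcription factor (0.81 lower) and ribosomal protein lists (0.44 lower), whose tests pointed up. ednrab was detected in 2 of 6 UN_RFP and 0 of 4 UN_BFP libraries, with UN_RFP 2 at 67.2 CPM.

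edgeR called 0 genes here (975 higher and 1664 lower at an unadjusted p under 0.05), voom called 8 higher and 157 lower, DESeq2 called 288 and 480, and edgeR with the vmhc to myh6 ratio in the model called 6 and 142. The voom calls fell to 31 in all without the 3 libraries of few detected genes and to 1 with log2 detected genes in the model. Without UN_RFP 6 edgeR called 10 higher and 160 lower genes, without UN_BFP 4 it called 6 and 2, and without any 1 of CI_BFP 1, CI_BFP 2, CI_BFP 3, CI_RFP 8 or UN_BFP 3 it called 2 lower genes.

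**Figure D3:**
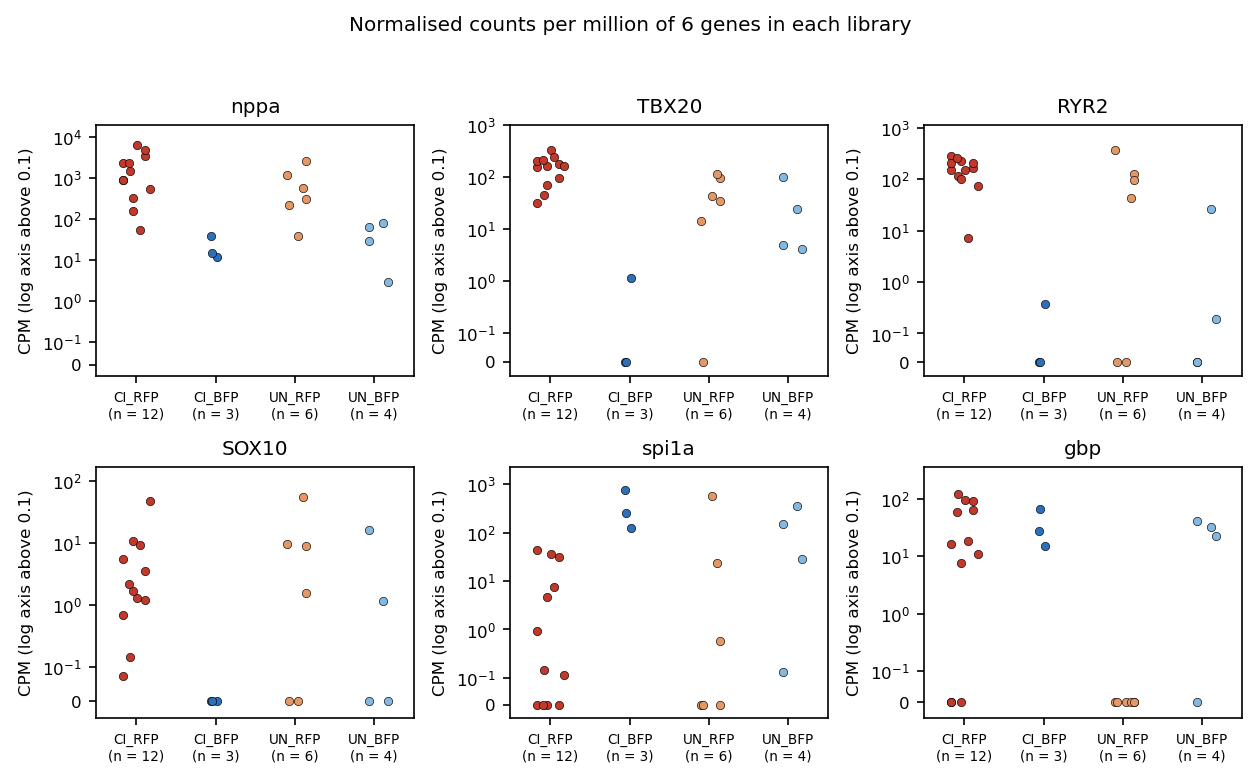
The level of selected genes is drawn per library in CPM on the vertical axis, which is linear near 0 and logarithmic above, by group. TBX20 lies at 158.8 ± 88.3 CPM in CI_RFP and 0.381 ± 0.660 CPM in CI_BFP, and gbp is at 0 in all 6 UN_RFP libraries.

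The comparison of CI_RFP with UN_RFP asks what differed in sox10-lineage cardiomyocytes after injury. edgeR called 4 genes here, where it called 5 in simulated data with no changed gene. Of 100 splits of the real libraries, the real one included, 16 gave as many, and the highest other gave 537. None of the 4 is therefore set apart from false calls by their number. gbp was the 1 higher gene that passed: it was detected in 9 of 12 CI_RFP libraries at 40.8 ± 44.1 CPM and in 0 of 6 UN_RFP libraries, an at least 692.9-fold higher level (log2 11.50, SE 2.33, edgeR adjusted p = 0.0153, voom adjusted p = 0.000715). It did not pass without UN_RFP 5 (adjusted p = 0.112), without UN_RFP 4 (0.0504) or without the 3 libraries of few detected genes (0.264). ANKH (ENSDARG00000071724), a pyrophosphate transporter, was detected in 9 of 12 libraries at 32.8 ± 39.6 CPM and in 0 of 6, at least 557.0-fold higher (edgeR adjusted p = 0.0628). GJA5 (ENSDARG00000069450), a gap junction connexin, was detected in 9 of 12 at 28.8 ± 38.1 CPM and in 0 of 6, at least 489.0-fold higher (edgeR adjusted p = 0.0701). ANKH and GJA5 complete the 3 higher genes of smallest p and did not pass.

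At an adjusted p under 0.1 there were 1448 higher and 62 lower genes, and the 6 list members named next were among them without passing 0.05. VEGFA (ENSDARG00000103542), the vascular growth factor, was detected in 12 of 12 CI_RFP libraries at 57.1 ± 37.4 CPM and at 1.95 ± 2.42 CPM in UN_RFP, 29.3-fold higher (edgeR adjusted p = 0.0912, voom adjusted p = 0.00864). LMNA, a nuclear lamin, stood at 94.9 ± 62.9 against 3.23 ± 3.88 CPM (edgeR adjusted p = 0.0912, voom adjusted p = 0.0379). RRM1, a subunit of ribonucleotide reductase, was detected in 9 of 12 libraries at 13.3 ± 14.4 CPM and in 0 of 6 (edgeR adjusted p = 0.0796). PRRX1 was detected in 6 of 12 at 26.03 ± 37.7 CPM and in 0 of 6 (edgeR adjusted p = 0.0796). COL6A2 stood at 51.1 ± 64.7 against 0.692 ± 1.36 CPM (edgeR adjusted p = 0.0912). The claudin CLDN5 (ENSDARG00000043716), of endothelial junctions, was detected in 8 of 12 at 8.76 ± 13.1 CPM and in 0 of 6 (edgeR adjusted p = 0.0912). The anchors did not part these groups: nppa (edgeR adjusted p = 0.504), nppb (edgeR adjusted p = 0.698), TBX20 (edgeR adjusted p = 0.543), TBX5 (edgeR adjusted p = 0.888) and SOX10 (edgeR adjusted p = 0.956) did not pass.

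The other 3 of the 4 calls were lower genes, each on the level of 1 to 3 UN_RFP libraries, no more in number than the false calls of the simulation. They are named because so few passed, after their values were seen. ACP5, a phosphatase of macrophages and osteoclasts, was detected in 0 of 12 CI_RFP and 3 of 6 UN_RFP libraries, with UN_RFP 6 at 139.6 CPM (edgeR adjusted p = 0.0153, voom adjusted p = 0.156), and it did not pass without UN_RFP 5 (adjusted p = 0.0899). dbpa was detected in 2 of 6 UN_RFP libraries, with UN_RFP 5 at 261.0 CPM (edgeR adjusted p = 0.0178, voom adjusted p = 0.323). Without UN_RFP 5 too few counts were left to test it, and with the vmhc to myh6 ratio in the model it did not pass (adjusted p = 0.131). spint2 was detected in 1 of 6, UN_RFP 6 at 156.4 CPM (edgeR adjusted p = 0.0407, voom adjusted p = 0.681), and without that library its log2 fold change was 1.74 (adjusted p = 0.538). It did not pass without any 1 of CI_RFP 4, CI_RFP 5, CI_RFP 7, CI_RFP 11 and UN_RFP 5 either (0.0504 to 0.112). Lower genes found in at least 75% of UN_RFP libraries did not pass. Of these ifi27.6, an interferon-induced gene, stood at 1.61 ± 3.02 against 60.02 ± 82.9 CPM (edgeR adjusted p = 0.0912, voom adjusted p = 0.0159). GSK3B, a kinase, stood at 8.69 ± 9.23 against 181.7 ± 438.2 CPM, and KPNA1, an importin, at 26.6 ± 17.5 against 250.3 ± 528.4 CPM (edgeR adjusted p = 0.0912 for both). UN_RFP 5 alone held 1076 CPM of GSK3B and 1326 CPM of KPNA1, and without the libraries of few detected genes the log2 fold changes were 1.42 and 0.86.

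Cell cycle genes had 29 of 32 positive folds and 19 members higher adjusted over the list alone (0.38 ± 1.11 in CI_RFP, -1.29 ± 0.70 in UN_RFP). The list did not rank above other genes by camera (adjusted p = 0.169), while fry gave an adjusted p = 0.0424. Immediate early and heat shock genes ranked above other genes (7.48 ± 0.63 against 5.30 ± 2.54, 41 of 50 positive, camera adjusted p = 0.00019, adjusted p = 0.901 with an estimated correlation, fry adjusted p = 0.0424), but turned in direction without CI_RFP 5, UN_RFP 1 and UN_RFP 5, the 3 libraries of few detected genes (adjusted p = 0.987). Extracellular matrix genes (33 of 34 positive, 1 higher adjusted over the list alone, camera adjusted p = 0.0127) and calcium handling genes (4.36 ± 1.61 against 2.12 ± 2.48, camera adjusted p = 0.0303) also ranked above other genes, each with adjusted p = 0.901 with an estimated correlation. The groups differed in their chamber myosins, vmhc exceeding myh6 in 4 of 12 CI_RFP and 4 of 6 UN_RFP libraries, and with the vmhc to myh6 ratio in the model the matrix list turned in direction (adjusted p = 0.539). Mitochondrially encoded genes ranked below (10.51 ± 1.69 against 11.63 ± 1.62, 13 of 13 negative, camera adjusted p = 2.51e-14, adjusted p = 0.574 with an estimated correlation), with MT-CO2, a cytochrome oxidase subunit, at 17250 ± 14650 against 42550 ± 32240 CPM (edgeR adjusted p = 0.148). These genes took 6.003 ± 3.45% of counts in CI_RFP (n = 12) and 12.2 ± 7.91% in UN_RFP (n = 6; exact permutation p = 0.0274, adjusted p = 0.255). Ribosomal protein genes ranked below (64 of 79 negative, camera adjusted p = 2.55e-15, adjusted p = 0.901 with an estimated correlation), with RPS28 at 134.4 ± 115.8 against 370.8 ± 363.1 CPM. Leukocyte (camera adjusted p = 4.24e-05), oxidative phosphorylation (4.73e-05) and erythrocyte lists (0.0303) ranked below, each with adjusted p = 0.901 with an estimated correlation. Their means differed in sign from the tests, being 0.26, 0.48 and 0.14 higher, and the oxidative phosphorylation list turned in direction with the ratio in the model (adjusted p = 0.530). The hypoxia and growth factor list did not pass by camera (adjusted p = 0.130) and passed by fry (adjusted p = 0.0424). The sarcomere list did not pass (camera adjusted p = 0.0526). Its test pointed down, although its mean was 0.79 higher and 24 of 33 members had a positive fold. The remaining 11 lists had camera adjusted p between 0.130 and 0.914. Leaving out 1 library ended the camera call of calcium handling (CI_RFP 1, 2, 5, 8 or 12, or UN_RFP 1, 3, 5 or 6, adjusted p = 0.0553 to 0.229) and extracellular matrix genes (CI_RFP 7, 10 or 11, or UN_RFP 1, 2 or 4, 0.0611 to 0.305). It also ended that of erythrocyte genes (CI_RFP 7, 10 or 11, UN_RFP 2, 3 or 5, or UN_BFP 4, 0.0536 to 0.224), oxidative phosphorylation genes (UN_RFP 2, 0.0865, or UN_RFP 4, 0.260) and leukocyte genes (UN_RFP 1, 0.300). Without the 3 libraries of few detected genes 3 of the 8 lists passed: calcium handling turned in direction (adjusted p = 0.987), and the leukocyte (0.746), erythrocyte (0.078) and extracellular matrix lists (0.0628) no longer passed.

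Of the genes with an unadjusted p under 0.05, 2354 were higher and 165 lower, and CI_RFP libraries also had more genes detected (11020 ± 3282, n = 12, against 6668 ± 3526, n = 6; exact permutation p = 0.0202, adjusted p = 0.255). edgeR called 1 higher and 3 lower genes, voom 1004 and 1, and DESeq2 843 and 41, while voom with log2 detected genes in the model called 4 in all. The edgeR count of 4 rested on single libraries: it was 0 without UN_RFP 5, 2 without UN_RFP 4, 160 without UN_RFP 6, 71 without CI_BFP 1 or CI_BFP 2 and 81 without CI_BFP 3. It was 16 without CI_RFP 1 or UN_RFP 2, 15 without CI_RFP 12, 14 without CI_RFP 2, 11 without CI_RFP 6, 10 without CI_RFP 8 or UN_BFP 1, 8 without CI_RFP 9, and 7 without CI_RFP 10 or UN_BFP 2. It was also 0 without the 3 libraries of few detected genes, with robust=FALSE and with the stricter filter.

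**Figure D4:**
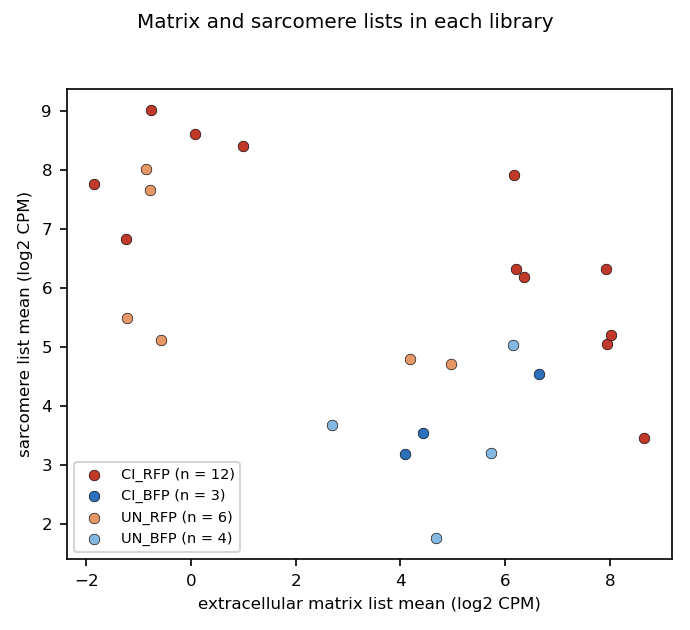
Each point is a library, with the mean log2 CPM of extracellular matrix genes on the x axis and of sarcomere genes on the y axis, by group. Matrix means of the CI_RFP libraries lie between -1.85 and 8.66, in a lower set of 5 and an upper set of 7 libraries.

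The comparison of CI_BFP with UN_BFP asks what differed after injury in the BFP gate. The 3 higher genes of smallest p were FLCN, SGSH and tpk2, none of which passed by edgeR. FLCN, folliculin, a regulator of nutrient sensing, was detected in 3 of 3 CI_BFP libraries at 32.4 ± 13.1 CPM and in 0 of 4 UN_BFP libraries, at least 506.0-fold higher (edgeR adjusted p = 0.510, voom adjusted p = 0.00469). SGSH, a lysosomal sulfatase, was detected in 3 of 3 at 23.3 ± 14.1 CPM and in 0 of 4, at least 363.1-fold higher (edgeR adjusted p = 0.510, voom adjusted p = 0.0243). tpk2 was detected in 3 of 3 at 15.9 ± 7.61 CPM and in 0 of 4 (edgeR adjusted p = 0.510, voom adjusted p = 0.0438).

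The 3 lower genes of smallest p were each detected in 3 of 4 UN_BFP and 0 of 3 CI_BFP libraries, and each had edgeR adjusted p = 0.510. PFKM stood at 10.1 ± 10.98 CPM in UN_BFP, at least 94.96-fold lower after injury, PPP1R27, a phosphatase regulator, at 8.68 ± 9.37 CPM, and prx at 27.0 ± 34.7 CPM. TBX20 stood at 0.381 ± 0.660 CPM in CI_BFP and 34.04 ± 46.4 CPM in UN_BFP (edgeR adjusted p = 0.510, voom adjusted p = 0.0584), and nppa at 21.4 ± 13.9 against 44.4 ± 35.2 CPM (edgeR adjusted p = 1). RYR2 stood at 0.127 against 6.62 ± 13.1 CPM, where UN_BFP 4 alone held 26.3 CPM. Ribosomal protein genes ranked below other genes in CI_BFP (7.76 ± 0.17 against 8.93 ± 0.22, 79 of 79 negative, camera adjusted p = 1.45e-14, adjusted p = 0.887 with an estimated correlation), with RPS28 at 48.4 ± 19.98 against 256.7 ± 183.6 CPM. So did oxidative phosphorylation genes (camera adjusted p = 0.00497), cardiac transcription factors (camera adjusted p = 0.0262) and the sorting line anchors (camera adjusted p = 0.0316, 1 lower adjusted over the list alone), each with adjusted p = 0.887 with an estimated correlation. Leukocyte genes (6.13 ± 0.89 against 3.74 ± 2.99, 36 of 42 positive, camera adjusted p = 0.00155) and cell cycle genes (21 of 32 positive, camera adjusted p = 0.0262) ranked above, with adjusted p = 0.887 for both with an estimated correlation. Leaving out 1 library ended the call of leukocyte genes (CI_BFP 2, CI_BFP 3 or UN_BFP 1, adjusted p = 0.0895 to 0.487), cell cycle genes (CI_BFP 1, CI_BFP 3, CI_RFP 1, UN_BFP 2 or UN_BFP 4, 0.0567 to 0.395) and oxidative phosphorylation genes (CI_BFP 1, 0.146, or UN_BFP 3, 0.155). It also ended that of cardiac transcription factors (CI_BFP 1, CI_BFP 3 or UN_BFP 1, 0.0681 to 0.108) and the anchors (CI_BFP 1, CI_BFP 3, UN_BFP 1, UN_BFP 3 or UN_BFP 4, 0.0519 to 0.155). MCM2, a DNA replication helicase subunit, was detected in 2 of 3 CI_BFP libraries (45.2 ± 67.8 CPM over all 3) and in 0 of 4 UN_BFP libraries (edgeR adjusted p = 0.510). The immediate early list did not pass (adjusted p = 0.0799), with HSPB1, a small heat shock protein, at 1199 ± 399.3 against 5816 ± 2138 CPM.

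edgeR called 0 genes (818 higher and 530 lower at an unadjusted p under 0.05), voom 41 higher and 8 lower, and DESeq2 183 and 268. Of its 6 lists past the threshold 2 passed without CI_BFP 1 or CI_BFP 3. By fry no list of this comparison passed (adjusted p = 0.985 for each).

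The interaction asks whether the gate difference itself differed between injured and uninjured hearts. TBX20, the anchor of smallest p, differed 416.5-fold between gates after injury and 1.49-fold before (interaction log2 8.06, SE 2.30, edgeR adjusted p = 0.253). SFRP1 (ENSDARG00000057678), a secreted Wnt antagonist, was detected in 4 of 4 UN_BFP libraries at 48.1 ± 52.8 CPM, 6 of 12 CI_RFP libraries, 0 of 3 CI_BFP and 0 of 6 UN_RFP libraries (edgeR adjusted p = 0.253, voom adjusted p = 0.0177). ANKH, FHL2, F2R, tpk2 and TESC complete the genes of smallest p, each with edgeR adjusted p = 0.253. TESC (ENSDARG00000030839), a calcium-binding protein, stood at 7.26 ± 2.65 CPM in CI_BFP and was detected in 0 of 4 UN_BFP libraries. Leukocyte genes ranked below other genes in the interaction (camera adjusted p = 1.59e-07), each of its 3 lists past the threshold having adjusted p = 0.869 with an estimated correlation. By fry no list of the interaction passed (the smallest adjusted p was 0.420). Immediate early and heat shock genes (41 of 50 positive, camera adjusted p = 0.000314) and cardiac transcription factors (15 of 19 positive, 3 higher adjusted over the list alone, camera adjusted p = 0.0344) ranked above. The last list did not pass without UN_BFP 1 (adjusted p = 0.116) or UN_RFP 5 (0.063), and without the 3 libraries of few detected genes neither it (0.222) nor the immediate early list (0.238) passed. The number of lists was 7 without CI_RFP 1, CI_RFP 2, UN_RFP 3 or UN_RFP 6, 6 without CI_RFP 5, CI_RFP 8, CI_RFP 12 or UN_RFP 4, and 5 without CI_BFP 2, CI_BFP 3, UN_BFP 2 or UN_BFP 3.

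edgeR called 0 genes in the interaction (1267 higher and 434 lower at an unadjusted p under 0.05), voom 7 higher and 1 lower, and DESeq2 499 and 166, and without CI_BFP 1 edgeR called 1. Across 14853 genes, which are not independent replicates, the edgeR gate differences after and before injury had r = 0.181 and rho = 0.21. By edgeR 0 genes were called in both. By voom 3 genes were higher in both gate comparisons, where 0.246 would be shared if the calls were independent, and 8 were lower in both, where 3.72 would be. For the injury differences of the 2 gates r was 0.028, edgeR shared 0 calls, and voom shared 6 higher genes where 2.77 would be shared if independent. All voom calls came from the same fit with the same spread per gene, so calls need not be independent even without a shared difference. These overlaps were not tested.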

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

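The tests on splits of the libraries for genes called and lists past the threshold of camera at the preset correlation, on detected genes in the gate comparison and on depth were set before their results were seen, and all other tests here were chosen after.

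After cryoinjury, cardiac lists had lower and the leukocyte list higher means in the BFP gate. The gates hardly differed in detected genes (11020 ± 3282 in CI_RFP, 10909 ± 3085 in CI_BFP, exact permutation p = 0.960), which argues against such a difference as the whole cause. A model with detected genes could therefore move little and adds no evidence of its own. In it the calcium difference was 3.85 (SE 1.09, before 3.82, SE 1.16) and the leukocyte difference -4.59 (SE 1.79, before -4.65, SE 1.91). A lower share of cardiomyocytes that raised every other cell type alike stays open, since leukocyte minus fibroblast list means (-1.45 ± 3.97 and 2.36 ± 2.54) had an exact permutation p = 0.165. RNA of other cells that diluted every cardiomyocyte transcript by the same factor stays open as well. Calcium handling minus sarcomere list means (-2.40 ± 0.53 in CI_RFP and -3.21 ± 0.38 in CI_BFP) had an exact permutation p = 0.0308, but 48.5% of the calcium values in CI_BFP were 0, too near the floor to decide it. Leukocyte RNA may be present in BFP-gate tubes, although the gate was meant to select cardiomyocytes. High shares were not confined to that gate. In percent of counts 10 of 12 CI_RFP libraries lay below all 3 CI_BFP libraries, but CI_RFP 9 (1.61%) and CI_RFP 6 (0.904%) lay above CI_BFP 1 (0.676%). The lineage of the cells, which the gate was meant to part, was not tested apart from the gate.

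Of the differences between CI_RFP and UN_RFP with an unadjusted p under 0.05, 93.4% were upward. Total counts were no higher in CI_RFP (8537887 ± 2437326, n = 12) than in UN_RFP (9206080 ± 1878704, n = 6, exact permutation p = 0.559), which argues against read depth as the whole cause. With every library thinned to 5644279 counts the share was 93.4%. Thinning reads does not even out the molecules captured per tube, so a difference in captured molecules stays open. The share was 94.5% without the 3 libraries of few detected genes, which argues against these as the whole cause. A lower number of detected genes in uninjured RFP-gate libraries stays open, since the tools differed: with log2 detected genes in the model the share was 40.6% by edgeR and 70.0% by voom (99.4% without it). With the vmhc to myh6 ratio in the model it was 82.7% by edgeR. The number of detected genes counts the same genes whose rise it would explain, so it does not part a technical loss of RNA from a smaller set of active genes, and the injury itself stays among the open explanations.

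Matrix genes were high in 7 CI_RFP libraries and near the floor in 5, of which 4 are the libraries with more vmhc and the other is CI_RFP 5. Both matrix and myh6 levels are shares of the counts of the same libraries, and the 7 were picked by their matrix level. Their relation therefore cannot decide whether atrial cardiomyocytes made the matrix RNA, and the same limit holds for the sarcomere list. Within the 7, the matrix list fell as myh6 rose (r = -0.91, exact permutation p = 0.000992, adjusted p = 0.00397; rho = -0.93, p = 0.00675; r = -0.86 without the 2 farthest libraries). It rose with 17 fibroblast markers outside the matrix list (r = 0.8, exact permutation p = 0.0196, adjusted p = 0.0262; rho = 0.86, p = 0.0238; r = 0.94 without 2) and fell against the sarcomere list (r = -0.82, exact permutation p = 0.0129, adjusted p = 0.0258; rho = -0.86, p = 0.0238; r = -0.71 without 2). Of 4 relations, that with detected genes had r = 0.1 (exact permutation p = 0.837; rho = -0.07, p = 0.906; r = 0.65 without 2). RNA of fibroblasts in some tubes may account for the matrix genes, although the gate was meant to select cardiomyocytes, and a difference between the cells of the heart's chambers was not tested apart from it.

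The interaction of gate and injury passed for the lists of leukocytes (camera adjusted p = 1.59e-07), immediate early and heat shock (0.000314) and cardiac transcription factors (0.0344), each with adjusted p = 0.869 with an estimated correlation.

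Only UN_BFP and UN_RFP were screened for a library set apart from its group, and the CI_RFP and CI_BFP libraries were not. Of 115 groups of values so screened, 22 held such a library, where chance sets about 1 in 20 apart if values are normally distributed. Of the 22, 20 were levels in CPM, all on the high side, and such levels are skewed, so their number is no sign of unusual libraries. In UN_BFP 4 the calcium handling list mean was 2.76 (others -0.896 to -0.354), atp2a2a 502.1 CPM (others 60.1 to 91.7), MYH7 3278 (others 0.407 to 464.2), nppb 317 (others 0 to 17.9) and RYR2 26.3 (others 0 to 0.194). Among other UN_BFP libraries, the hypoxia list mean was 1.23 in UN_BFP 3 (others 2.28 to 2.44), myh6 92.4 and SOX10 16.5 CPM in UN_BFP 1 (others 0, and 0 to 1.16), and RPS28 529.5 CPM in UN_BFP 2 (others 141.8 to 200). UN_RFP 5 held dbpa at 261 CPM (others 0 to 32.7), GSK3B at 1076 (others 0 to 6.24), KPNA1 at 1326 (others 4.48 to 112) and mlip at 588.2 (others 0.114 to 108.8). UN_RFP 6 held ACP5 at 139.6 CPM (others 0 to 11.9), COL6A2 at 3.4 (others 0 to 0.746) and spint2 at 156.4 (others 0). UN_RFP 3 held SOX10 at 56.6 CPM (others 0 to 9.73), LMNA at 10.5 (others 0 to 3.42) and PTGS2 (ENSDARG00000010276) at 0.224 (others 0). UN_RFP 2 held atp2a2a at 2996 CPM (others 443.9 to 1380) and ednrab at 67.2 (others 0 to 0.114), and UN_RFP 4 held TBX5 at 65.7 CPM (others 0 to 18.7).

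For 2 of 25 counts under 5% of the splits of the libraries gave as many, where 100 splits were drawn, or all 35 for CI_BFP vs UN_BFP, the real one included. Counts whose real value was 0 are reached by every split, so they could not come out this low. Of the counts that could, chance brings about 1 in 20 this low, so over those it was not excluded for these 2. They were the list that passed with an estimated correlation in CI_RFP vs CI_BFP (2 splits with as many, real 1, highest other 1) and the genes of CI_RFP vs UN_RFP at an unadjusted p under 0.05 (3 splits with as many, real 2519, highest other 3175). Nor was chance excluded for the counts above 0 that follow, while those with a real value of 0 cannot bear on it. For edgeR, splits with as many genes numbered 100 in CI_RFP vs CI_BFP (real 0, highest other 6), 100 in UN_RFP vs UN_BFP (0 and 514), 16 in CI_RFP vs UN_RFP (4 and 537), 35 in CI_BFP vs UN_BFP (0 and 2) and 100 in the interaction (0 and 28). For voom they numbered 8 (808 and 2554), 17 (165 and 1178), 5 (1005 and 2654), 14 (49 and 709) and 29 (8 and 719) in the same order. For the number of lists past the threshold they numbered 28 (12 and 15), 6 (14 and 15), 54 (8 and 15), 2 (6 and 7) and 88 (3 and 14). With an estimated correlation the other 4 comparisons had 0 lists, which every split must reach (100, 100, 35 and 100 splits, highest other 1, 1, 0 and 0), so these 4 could not decide it. Genes at an unadjusted p under 0.05 by edgeR were as many in 12 splits of CI_RFP vs CI_BFP (1385 and 3049), 39 of UN_RFP vs UN_BFP (2639 and 4983), 19 of CI_BFP vs UN_BFP (1348 and 2390) and 53 of the interaction (1701 and 3049). Some splits called many times the real count, which points to a structure of the libraries other than their groups, and no test here related those splits to any feature of the libraries.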

How the results depend on the processing

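No paired analysis was possible because the replicate numbers follow the order of deposition and no label ties a library of one group to a library of another. The upper quartile factors could not be computed, since the upper quartile of UN_RFP 5 is 0, and were not run. Alternatives with voom beside another choice, and the vmhc to myh6 ratio, were chosen after seeing the data. Causes were not tested except where stated.

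Genes called in CI_RFP vs CI_BFP (0 by edgeR) were 457 by DESeq2, 808 by voom, 1 each with RLE and TMMwsp factors, 293 without a filter, 11 with only the groups compared, 50 with detected genes as a covariate, 662 by voom without the 3 libraries of few detected genes, 505 by voom with that covariate and 139 with the ratio. For UN_RFP vs UN_BFP (0) they were 768 by DESeq2, 165 by voom, 27 without a filter, 31 by voom without the 3 libraries, 1 by voom with the covariate and 148 with the ratio. For CI_RFP vs UN_RFP (4) they were 884, 1005, 513 without a filter, 0 with a stricter filter, with robust=FALSE and without the 3 libraries, 35 with the covariate, 183 by voom without the 3 libraries and 4 by voom with the covariate. For CI_BFP vs UN_BFP (0) they were 451, 49, 25 by voom without the 3 libraries and 23 by voom with the covariate. For the interaction (0) they were 665, 8, 2 without a filter and 1 by voom without the 3 libraries. DESeq2 also called 353, 175, 105, 241 and 270 genes in simulated data with no changed gene. Leaving out 1 library gave 0 to 9 genes in CI_RFP vs CI_BFP, 0 to 170 in UN_RFP vs UN_BFP, 0 to 160 in CI_RFP vs UN_RFP and 0 to 1 in the interaction.

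With an estimated correlation 1, 0, 0, 0 and 0 lists passed, against 12, 14, 8, 6 and 3. Without the 3 libraries 3 lists passed in CI_RFP vs UN_RFP and 1 in the interaction, and with the ratio 8 in the interaction. Leaving out 1 library gave 2 to 7 lists in CI_BFP vs UN_BFP and 2 to 7 in the interaction. In CI_RFP vs UN_RFP the calcium handling and immediate early lists turned without the 3 libraries (adjusted p = 0.987 each), and the extracellular matrix (0.539) and oxidative phosphorylation lists (0.530) with the ratio. Over all comparisons, a prior count of 0.5 ended 3 list calls and kept 40, and the ratio ended 1 besides the 2 that turned. Exact permutation of list means gave 0 of 88 past the threshold (the smallest adjusted p was 0.0967, for calcium handling and the anchors in CI_RFP vs CI_BFP, p = 0.0022, the smallest that 455 regroupings can give), and without UN_RFP 6 it gave 2 each in CI_RFP vs CI_BFP and CI_RFP vs UN_RFP.

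log2 fold changes that turned in direction were, in CI_RFP vs CI_BFP, MYH7 -2.04 and gata4 1.30 by voom. In UN_RFP vs UN_BFP they were HAND2 -0.14 by DESeq2, -0.16 by voom, -0.14 with RLE, -0.058 without a filter and -0.011 with only the groups compared, and gata4 -0.17 by DESeq2, -1.23 by voom and -0.18 with RLE. In CI_RFP vs UN_RFP they were MYH7 -4.91, gata4 0.67, MYL7 -0.086, GSK3B 1.31 and KPNA1 0.093 by voom, NKX2-5 -0.11 by DESeq2 and -0.11 with RLE, HAND2 -0.11 and GSK3B 1.49 with the covariate, and GSK3B 1.42 and KPNA1 0.86 without the 3 libraries. In CI_BFP vs UN_BFP they were MYH7 1.65, gata4 -1.85, myh6 0.027 and NKX2-5 0.48 by voom, and gata4 -0.013 with TMMwsp, -0.022 without a filter, -0.029 with only the groups compared and -0.033 without mitochondrially encoded genes, and with the ratio gata4 -0.236 and myh6 0.999. In the interaction they were MYH7 -6.56, gata4 2.53 and MYL7 -1.56 by voom, MYL7 -0.95 by DESeq2 and -0.95 with RLE, and myh6 -0.484 with the ratio. The difference in detected genes in CI_RFP vs CI_BFP was -98.0 at a count of at least 5.

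Leaving out 1 library turned these: detected genes in CI_RFP vs CI_BFP, -1053 to 1860; gata4, -1.05 to 1.87 there, -0.46 to 0.79 in UN_RFP vs UN_BFP, -1.07 to 0.14 in CI_RFP vs UN_RFP, -2.29 to 0.63 in CI_BFP vs UN_BFP and -1.21 to 1.70 in the interaction. In UN_RFP vs UN_BFP, HAND2 ranged from -0.46 to 0.56 and SOX10 from -0.13 to 5.01. In CI_RFP vs UN_RFP, GSK3B ranged from -5.33 to 1.61, HAND2 from -0.015 to 0.80, SOX10 from -1.96 to 0.80 and spint2 from -10.86 to 1.74. In CI_BFP vs UN_BFP, MYH7 ranged from -2.46 to 0.29, NKX2-5 from -1.54 to 0.76, RYR2 from -8.83 to 0.96 and myh6 from -10.76 to 5.68. In the interaction, MYL7 ranged from -0.48 to 0.68, NKX2-5 from -0.26 to 2.09 and myh6 from -3.22 to 13.28. Of the other fold changes of named genes over all libraries left out in turn, 2742 kept direction and side of the threshold, 78 passed newly and 8 no longer passed.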

Other observations

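Among CI_RFP libraries, those with more vmhc were CI_RFP 1 (31000 CPM), CI_RFP 2 (41360), CI_RFP 8 (26120) and CI_RFP 12 (53550), and their IRX1 levels were 186.4, 196.4, 6.48 and 113.1 CPM. Calcium handling list means overlapped, at 5.11 to 6.46 in these 4 and 1.35 to 6.13 in the 8 with more myh6. In UN_RFP they were -1.59 to 5.09 in the 4 libraries with more vmhc and 2.17 and 2.67 in the 2 with more myh6. Among those with more myh6, CI_RFP 9 held 4334, CI_RFP 3 held 3826 and CI_RFP 6 held 3293 CPM of myh6, and CI_RFP 11, with the least (238.7 CPM), had the highest matrix list mean of the 25 libraries (8.66). Among UN_RFP libraries, UN_RFP 2 and UN_RFP 4 held 21770 and 19420 CPM of vmhc, and UN_RFP 3 and UN_RFP 6 held 687.1 and 872.7 CPM of myh6. These values were picked after they were seen and were not tested, since the libraries would be grouped by the genes measured.

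With the vmhc to myh6 ratio in the model, more genes passed the edgeR test in both gate comparisons, although the ratio is itself measured from tested genes. After cryoinjury these included F2R (adjusted p = 0.00841), TNNT2 (adjusted p = 0.0136), hsp90aa1.1 (adjusted p = 0.0347), cpt1ab (adjusted p = 0.0428) and TBX5 (adjusted p = 0.0474), while ADAM11 (adjusted p = 0.0553) did not pass. In uninjured hearts gbp (adjusted p = 0.0133), PTGS2 (adjusted p = 0.0133), tspan34b (adjusted p = 0.0165), COL6A2 (adjusted p = 0.0169), PRRX1 (adjusted p = 0.0276), CCND1 (adjusted p = 0.0306), nppa (adjusted p = 0.0447) and mlip (adjusted p = 0.0494) passed. In CI_RFP vs UN_RFP gbp (adjusted p = 0.0117), ACP5 (adjusted p = 0.0067) and spint2 (adjusted p = 0.0362) passed, and dbpa (adjusted p = 0.131) did not.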
